A study of Mus musculus with 2 samples.

How the data were processed

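H3K9me3, the trimethylation of lysine 9 of histone H3, was measured by ChIP-seq in limb tissue of mouse embryos of the B6NCrl strain at embryonic day 11.5. There was 1 group of 2 biological replicates. Replicate 1 was a pool of limbs from 109 embryos and replicate 2 a pool from 88 embryos, both of mixed sex. The deposited data were 4 peak lists on the mm10 build: a list for each replicate, a pooled list and a replicated list. According to the text deposited beside the lists, each replicate list came from that replicate's filtered alignments and a control, the pooled list from the alignments of both replicates together, and the replicated list from the pooled list and both replicate lists. The aligner, the peak caller, their versions and the thresholds were not given in the sources used here.

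Each deposited list gave a position, a display score, a fold enrichment over the control, the −log10 of a p-value and of a q-value, and the offset of the summit for every peak. The display score, deposited by the authors, was not used. The fold enrichment is a ratio of signal in the immunoprecipitate to the control, computed by the authors' peak caller. The −log10 p and −log10 q were likewise deposited as the authors' caller wrote them. These values belong to single peaks and were used to describe, rank or filter peaks, and to set both replicates' values side by side at shared peaks. The lists hold no read counts, so the sequencing depth of each library is unknown, and no depth correction was possible. Intervals given for shares of peaks are exact binomial 95% intervals that treat peaks as independent and cover counting error only. Where a share was 0, the limit is that of 3 counts of the total.

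Positions were compared with the GRCm38.p6 reference sequence and its GENCODE annotation (release M21), the build named mm10 in the lists. All peaks on assembled chromosomes lay within the reference lengths. Peaks on contigs without a place on a chromosome were left out of every comparison except those of the series lists with the replicate lists and of fold enrichment between replicates. They are described separately. This left 26686 of 26934 peaks of replicate 1, 55064 of 55383 of replicate 2, 9825 of 10086 pooled peaks and 7240 of 7475 replicated peaks. The replicated list was the main set for every question about location. Coordinates are 1-based.

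Each comparison used a rotation test, a permutation test that moves a whole peak set. The gap-free sequence of chromosomes 1 to 19, X and Y was joined into a circle, and the peak set was shifted as a block by a random distance, 1000 times with a fixed seed. This keeps the spacing of peaks and of genes, so that neighbouring members of a gene family are not counted as independent. Tests were two-sided, with p as 2 times the smaller tail, the observed arrangement counted. The smallest p that 1000 shifts can give is 0.002. For speed, 200 shifts were drawn for the sequence content of the replicate lists (smallest p 0.00995) and 100 for overlaps of at least 50% (smallest p 0.0198). The p-values were adjusted by Benjamini-Hochberg within each family, and 0.05 was the threshold. Those of replicate overlap, of last exons and of the tests under other observations were left unadjusted. The p-values describe the placement of peaks along 1 genome and do not measure the spread between animals, since there was 1 group.

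The families were as follows. Peak centres were placed, in this order, in promoters (within 1 kb of a transcription start site, TSS), exons, introns or intergenic sequence, which made 4 tests. For 18 gene lists, the share of genes with at least 1 bp of a replicated peak in the gene body was compared with the share of all other protein-coding genes, out of 21938, and the test statistic was the difference between both shares. The lists were Zfp genes (zinc finger proteins, by symbol), olfactory receptors, vomeronasal receptors, clustered protocadherins, keratins and keratin-associated proteins, Hox clusters, ribosomal proteins, genes at imprinted regions, germline genes, limb patterning genes, housekeeping genes, the H3K9 methylation machinery, and markers of neurons, liver, muscle and heart, blood, endothelium and epidermis. The lists share 9 genes between Hox and limb patterning and 6 between keratins and epidermis. Zfp genes share 1 gene with the germline list and 2 with the H3K9 machinery, and ribosomal proteins share 1 with the germline list. Coverage of the last exon was set against the rest of the gene in genes of at least 2 exons. Peak bases per Mb were computed for 21 chromosomes, and GC content, the CpG observed/expected ratio and soft-masked (repeat) content for the bases in peaks. Exact matches of 17 or 18 bases to tRNA primer binding sites, the sequences at which reverse transcription of LTR retroelements starts, were located on both strands for 6 tRNAs, and those within 1 kb of a replicated peak were counted.

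Groups, lists, tests and the rule for naming genes were fixed before the data were examined. The rule named the 3 members of each list with the most covered bases, every marked gene of the imprinted, limb patterning and housekeeping lists where there were 10 or fewer, the 10 protein-coding genes with the most covered bases, and the 10 with the highest covered share among genes of at least 5 kb. It also named the 5 replicated peaks with the highest fold enrichment, the 5 longest merged replicated peaks, and for each replicate the 3 highest peaks with no overlap in the other. A gene or region named outside this rule is said to have been chosen after its values were seen.

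The alternatives were other overlap minimums, peaks with −log10 q of at least 2, equal numbers of top peaks, peaks merged within 1 kb, the peaks of a single replicate or the pooled peaks in place of replicated peaks, the 50% of replicated peaks with the highest fold enrichment, other promoter and primer site distances, a minimum of 10% of the gene body, 10000 random lists matched on gene length, Fisher's exact test, and X and Y left out. Added after the data were seen were the share of a list alone as the statistic, and replicated peaks overlapped by both replicates.

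The tests were checked on simulated data with 200 shifts each. Among 720 tests of the gene lists on 40 rotated peak sets, 5.56% gave p under 0.05, with 3.61% of 554 tests for lists with a marked gene and 12.0% of 166 tests for lists with none. A list with no marked gene takes its p from the other genes' share, so its p is too small, and the p of the list's own share is given beside it. With peaks planted in 80 Zfp genes, the list test and the last exon test passed in 20 of 20 draws, and the planted overlaps were counted as made in 20 of 20 draws. The count of overlapped peaks of replicate 1 was also made with bedtools, which gave 5764 as well. The work used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Matplotlib 3.10.9 and bedtools 2.31.1.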

Results

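H3K9me3, a histone mark of heterochromatin and silenced genes, was mapped by ChIP-seq in mouse limb tissue at embryonic day 11.5, when the limb buds are being patterned. The series held 2 biological replicates of 1 group, pools of limbs from 109 and 88 embryos, so that the design asks where the mark lies and how far both replicates show it at the same places. The lists held 26934 peaks for replicate 1, 55383 for replicate 2, 10086 for both replicates pooled and 7475 replicated peaks. Replicated peaks on assembled chromosomes covered 2.41 Mb, 0.0909% of the gap-free genome, with a median width of 260 bases and a median fold enrichment over the control of 3.28 (quartiles 2.96 and 3.75, highest 14.6), as the authors' caller gave it. The replicate lists covered 6.27 Mb (0.237%) and 14.3 Mb (0.542%). Their median fold enrichments were 3.15 and 3.23. The lowest −log10 p listed was 2.01 in replicate 1 and 2.04 in replicate 2, and a q below 0.05 was given for 18.4% of peaks in replicate 1, 45.1% in replicate 2 and 33.7% of replicated peaks. Sequencing depth could not be read from the lists.

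Both replicates placed H3K9me3 at shared sites far more often than rotated peak sets did, while most listed peaks were found in a single replicate. Of the 26686 peaks of replicate 1 on assembled chromosomes, 5764 (21.6%, 95% interval 21.1 to 22.1) were overlapped by at least 1 bp by a peak of replicate 2. Of the 55064 peaks of replicate 2, 5586 (10.1%, 9.89 to 10.4) were overlapped by replicate 1. Rotated sets gave 1.01% and 0.493%, so the overlaps were 21.4-fold and 20.6-fold above rotation (permutation p = 0.002 for each, rotation test, the smallest p that 1000 shifts can give). Strong peaks were shared more often. Among the 10% of peaks with the highest −log10 p, 48.8% of replicate 1 and 33.1% of replicate 2 were overlapped, against 13.5% and 5.27% in the lowest 10%. With −log10 q of at least 2 in both lists, 39.8% of 2114 peaks of replicate 1 and 5.77% of 13605 of replicate 2 were overlapped. Requiring at least 50% of the peak gave 16.9% and 5.94%, and a reciprocal 50% gave 11.2% and 5.405%.

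**Figure D1:**
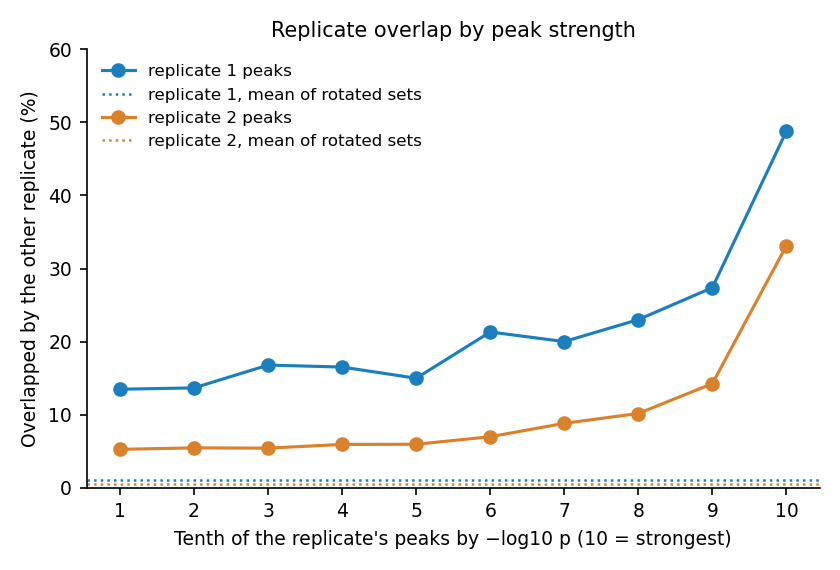
Share of each replicate's H3K9me3 peaks overlapped by at least 1 bp by the other replicate (y axis, percent), in 10 equal steps of the replicate's peaks ranked by the authors' −log10 p (x axis, 10 is the strongest). The strongest step of replicate 1 reached 48.8% and that of replicate 2 33.1%, and dotted lines give the means of rotated sets, 1.01% and 0.493%.

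The peaks that the fold enrichment of replicate 1 placed highest without any overlap in replicate 2 lay in Pax7 (chromosome 4, 139816020 to 139816245), in Mpp6 (chromosome 6, 50172675 to 50173093) and at Galr3 and Gcat, both of which it touched (chromosome 15, 79042531 to 79042821), each at 5.46-fold. The corresponding peaks of replicate 2 were in AU041133 (chromosome 10, 82152214 to 82152459, 8.41-fold), on chromosome 4 at 147404482 to 147404819 with Zfp978 as the gene of the nearest TSS (7.90-fold), and in the protocadherin region of chromosome 18 at 37532686 to 37532990, nearest to the TSS of Pcdhb22 (7.76-fold).

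All 7475 replicated peaks were entries of the pooled list. Of these, 62.7% (95% interval 61.6 to 63.8) were covered over at least 50% of their length by peaks of replicate 1, 94.0% (93.4 to 94.5) by replicate 2, 56.8% (55.7 to 58.0) by both and 13 peaks by neither. Of the pooled peaks, 42.1% (41.2 to 43.1) were found in both. At 1 bp, 4761 replicated peaks were overlapped in both replicates. For each replicate, the highest value among its peaks overlapping a replicated peak was taken. Across these 4761 peaks, which are not independent replicates, the fold enrichments of both replicates had a Spearman rho of 0.209 (95% interval 0.182 to 0.236) and a Pearson r of 0.322 on the log2 scale. The interval treats the peaks as independent. The median fold enrichment was 3.36 in replicate 1 and 3.88 in replicate 2, and the value of replicate 2 was the larger at 75.2% of the peaks. Replicate 2 listed more peaks, and taking the highest of several could raise its values.

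Clustered protocadherins, neuronal cell adhesion receptors encoded in 3 tandem arrays on chromosome 18, carried many replicated peaks. The window from 37 to 38 Mb held 159 peaks and 3.23% of all replicated-peak bases, the most of any 1-Mb window. A replicated peak lay in 49 of 57 genes (86.0%), against 7.48% of other protein-coding genes and a mean of 11.2% (95% range 0 to 56.1) for the same list in rotated sets (adjusted permutation p = 0.006, rotation test with Benjamini-Hochberg adjustment). In the replicates' own lists, which marked more protein-coding genes of every kind, the share was 91.2% in replicate 1 and 100% in replicate 2. These shares therefore cannot be set against the 7.48%. A replicated peak lay within 1 kb of a TSS in 40 of the 49 genes. The annotated bodies of these genes overlap, so that the 49 genes form 20 separate blocks with 144 peaks. Coverage differed between the arrays. Replicated peaks covered 28.5% of the Pcdhg array (37661793 to 37841873, 80 peaks), 5.41% of the Pcdhb array (37264938 to 37524479, 43 peaks) and 4.55% of the Pcdha array (36930184 to 37187661, 33 peaks). Replicate 1 alone covered 21.5%, 4.31% and 3.88%, and replicate 2 38.1%, 16.2% and 8.83%. Replicated peaks did not run through whole arrays. In the Pcdhg array they covered up to 71.3% of a 10-kb bin, and none lay between 37780000 and its end. In the Pcdha array none lay between 37060000 and its end. Of single genes, Pcdhga1, whose annotated body spans the whole Pcdhg array, held 80 peaks with a highest fold enrichment of 7.49, and Pcdhga2 (29.2% covered) and Pcdhga3 (28.5%) lie inside it. Pcdhgb1, Pcdhga4, Pcdhgb2 and Pcdhga5 in the same array were covered over 28.3%, 28.1%, 27.4% and 27.2%. Gm42416, Gm37013 and Gm37388, transcript models that run across the arrays, had the most covered bases of all protein-coding genes (82275, 79604 and 79156 bases).

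**Figure D2:**
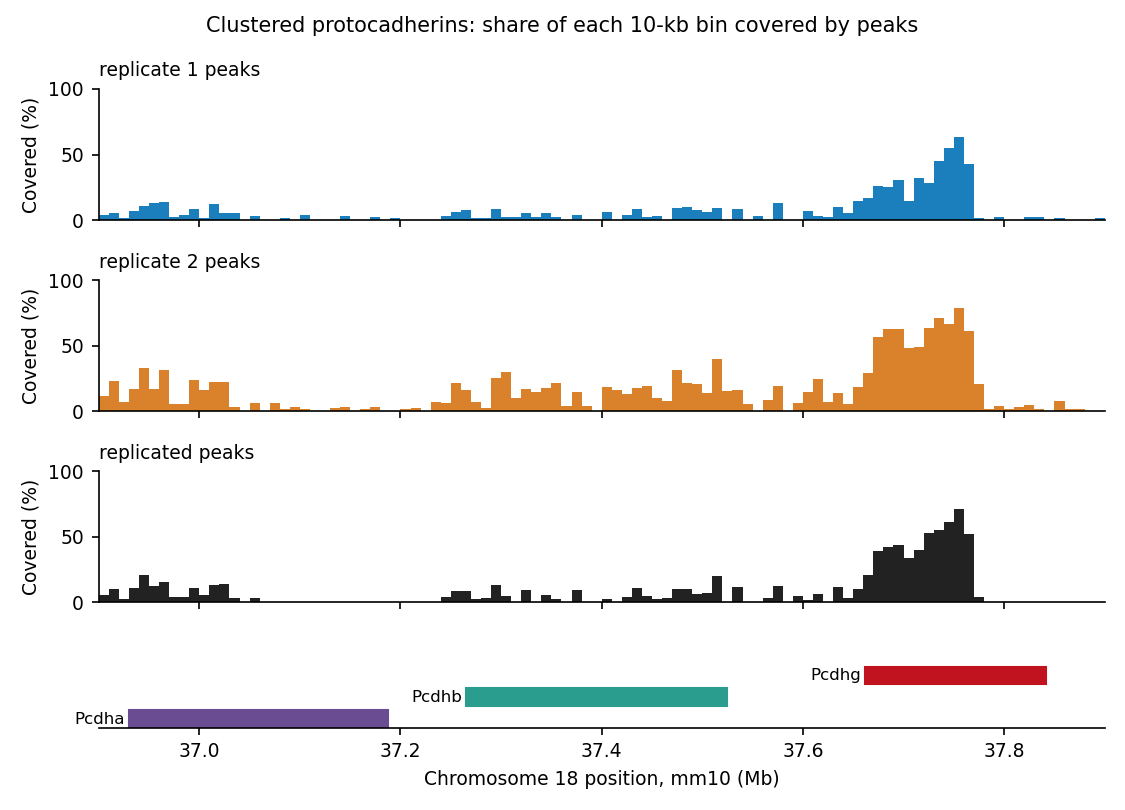
Share of each 10-kb bin covered by H3K9me3 peaks (y axis, percent) along the clustered protocadherins of chromosome 18 (x axis, Mb on mm10), for replicate 1, replicate 2 and replicated peaks, with the 3 gene arrays drawn as bars. The Pcdhg array, covered over 28.5% by replicated peaks, stands above Pcdhb (5.41%) and Pcdha (4.55%) in all 3 tracks.

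Genes at imprinted regions, which are expressed from a single parental allele, were marked in 28 of 39 cases (71.8%, against 7.58% of other genes and 8.48% in rotated sets, range 0 to 17.9; adjusted permutation p = 0.006). The 28 genes formed 22 blocks with 79 peaks. Of them, 12 had a peak within 1 kb of a TSS and 25 were covered in both replicates' own lists. Most bases were covered in Gnas (chromosome 2, 174284320 to 174346744, 11 peaks, 8.27% of the gene, highest fold enrichment 4.86), Mest (chromosome 6, 30723547 to 30748465, 7 peaks, 13.2%, 4.38) and Peg3 (chromosome 7, 6703892 to 6730431, 3 peaks, 11.8%, 3.72). Replicates 1 and 2 covered 6.84% and 11.7% of Gnas, 9.67% and 16.9% of Mest, and 10.2% and 21.5% of Peg3.

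Zfp genes, which encode zinc finger proteins and include many KRAB zinc finger repressors of retroelements, were marked in 105 of 391 cases (26.9%, against 7.33% of other genes and 4.86% in rotated sets, range 2.56 to 7.93; adjusted permutation p = 0.006). The share was 41.2% with the peaks of replicate 1 alone and 58.3% with those of replicate 2. Both lists also marked more of the other protein-coding genes, so these shares cannot be set against the 7.33%. Zfp873 (chromosome 10, 82048123 to 82064745) held 14 peaks over 42.1% of its length (25.7% in replicate 1 and 54.4% in replicate 2), with a highest fold enrichment of 5.80. Zfp180 (chromosome 7, 24081924 to 24107713) held 9 peaks over 23.5%, and Zfp110 (chromosome 7, 12834761 to 12850577) 9 peaks over 31.0%.

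Within Zfp genes the mark was denser in the last exon than in the rest of the gene. In the 387 Zfp genes with at least 2 exons, replicated peaks covered 5.49% of last exon bases and 0.601% of the rest of the gene bodies, a ratio of 9.12 (rotated sets: median 0.855, 95% range 0 to 3.85; permutation p = 0.002, rotation test). The last exon of such genes usually encodes the zinc finger array. Of these genes, 102 had a peak in the body, 77 in the last exon and 25 in the body but not in the last exon. A peak lay within 1 kb of the TSS, inside or upstream of the gene, in 5 (Zfp3, Zfp382, Zfp541, Zfp872 and Zfp988, named after their values were seen). At least 50% of the last exon was covered in 15. The last exon was covered over 94.6% in Zfp146, 87.9% in Zfp180, 55.2% in Zfp110 and 44.6% in Zfp873. It held the smaller part of the covered bases in each, 1855 of 4648, 2910 of 6049, 1205 of 4905 and 921 of 7004, in that order. In others it held the larger part, as in Zfp777 (1405 of 1752), named after its values were seen. In 19998 other protein-coding genes the ratio was 1.31 (permutation p = 0.126), and it was past the threshold with the peaks of replicate 1 alone (1.42, permutation p = 0.004) and of replicate 2 alone (1.496, permutation p = 0.002). With the peaks of replicate 1 alone the ratio in Zfp genes was 6.93 and with those of replicate 2 alone 5.81, both with permutation p = 0.002.

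Germline genes, used in meiosis and in piRNA defence of germ cells, were marked in 14 of 47 cases (29.8%, against 7.63% of other genes and 6.32% in rotated sets, range 0 to 14.9; adjusted permutation p = 0.006). Each of the 14 held a single peak, and 10 of these genes had a peak within 1 kb of the TSS. Ddx4, a germ cell RNA helicase, was marked at its TSS (chromosome 13, gene at 112598333 to 112652475, fold enrichment 5.65), as was Taf7l (X, 134460118 to 134476490, 3.75). Meioc, a regulator of meiotic entry, had a peak of 1076 bases inside the gene (chromosome 11, 102663716 to 102682237, 4.54). With the peaks of replicate 2 alone the difference stayed positive at 10.3 percentage points after rotation but was no longer past the threshold (adjusted permutation p = 0.360), while the share, 53.2%, lay above its rotated range of 23.4 to 48.9. No germline gene was covered over at least 10% of its body.

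Vomeronasal receptors, pheromone receptors in tandem arrays, were marked in 47 of 327 cases (14.4%, against 7.58% of other genes and 2.78% in rotated sets, range 0.612 to 6.42; adjusted permutation p = 0.006). Vmn2r60 held 7 peaks over 2.09% of its body, Vmn2r56 4 peaks over 2.73% and Vmn2r53 4 peaks over 2.41%, the last with no base covered in replicate 1. With the pooled list the adjusted permutation p was also 0.00599. With the peaks of replicate 2 alone the adjusted permutation p was 0.365, with a share of 32.1% above its rotated range of 10.7 to 28.1. With those of replicate 1 alone the difference from other genes after rotation turned from 10.2 to −5.70 percentage points (adjusted permutation p = 0.102), with a share of 14.7% inside its rotated range of 5.50 to 18.97. Counting peaks within 2 kb of a TSS gave 0.113, and a minimum of 10% of the body 0.665. Olfactory receptors, the largest family tested, were marked in 34 of 1093 cases (3.11%, against 7.92% of other genes and 1.40% in rotated sets, range 0.457 to 3.11; adjusted permutation p = 0.769). Fisher's exact test, which takes no account of gene length, placed them 4.81 percentage points below other genes (adjusted p = 6.40e-10). With the peaks of replicate 1 alone the rotation test of this difference gave an adjusted permutation p of 0.00719, while the family's own share, 6.04%, lay inside its rotated range of 3.66 to 8.79. With those of replicate 2 alone the share was 16.2%, above its rotated range of 7.04 to 14.9, and the difference was not past the threshold (adjusted permutation p = 0.776). Olfr398 (chromosome 11) was covered over 19.9%, Olfr1349 over 10.8% and Olfr139 over 6.93%.

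Genes that pattern the limb bud were marked in 2 of 54 cases (3.70%, against 7.69% of other genes). This share lay inside the range of rotated sets (5.05%, range 0 to 11.1). The difference from other genes was not past the threshold (adjusted permutation p = 0.455, rotation test). Bmp7, a bone morphogenetic protein, had a peak of 382 bases in its last exon (chromosome 2, 172868012 to 172940321, fold enrichment 3.91), and Wnt3 a peak of 200 bases (chromosome 11, 103774150 to 103817957, 3.44). The replicates' own lists marked more of these genes, 20 in replicate 1 and 16 in replicate 2. With the peaks of replicate 1 alone, and with −log10 q of at least 2, the list lay above other genes relative to rotation (adjusted permutation p = 0.102 and 0.987). Within 2 kb of a TSS, and at 10% of the body, no limb gene was marked, and the test of a list with no marked gene rests on the share of other genes, so that no call was drawn at these settings.

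No replicated peak lay in any of 39 Hox cluster genes, 105 keratin and keratin-associated genes, 79 ribosomal protein genes, 44 housekeeping genes or 20 epidermal genes. With each gene counted as independent, a count of 0 allows shares of up to 7.69%, 2.86%, 3.797%, 6.82% and 15%, in that order. Neighbouring genes, such as those of the Hox clusters, are not independent, so that the limits of lists with such genes are too low. The tests of the difference from other genes gave adjusted p of 0.006 for housekeeping genes and 0.00719 for the other 4 lists. These p came from the share of other genes. Tested by the list's own share, an alternative chosen after the data were seen, the adjusted p was 0.860 for housekeeping genes and 1 for the other 4 lists, so that no depletion of these lists was detectable in the replicated list. In the replicates' own lists, Hox cluster genes were marked in 25.6% and 15.4% of cases in replicates 1 and 2, keratin genes in 1.90% and 8.57%, ribosomal protein genes in 7.59% in each, housekeeping genes in 11.4% and 20.5%, and epidermal genes in 25% and 30%. By these lists the difference from other genes was past the threshold for ribosomal protein genes in replicates 1 and 2 (adjusted permutation p = 0.012 and 0.045) and for keratin genes in replicate 1 (adjusted permutation p = 0.00719). These p also came mainly from the share of other genes, as the lists' own shares lay inside their rotated ranges, 0 to 8.86% and 2.53 to 13.9% for ribosomal protein genes and 0 to 10.5% for keratin genes.

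Markers of other tissues and the H3K9 machinery were not past the threshold in the replicated list. Neuronal genes were marked in 5 of 32 cases (15.6%, adjusted permutation p = 0.595). Slc17a7, a vesicular glutamate transporter, held 3 of the 8 peaks over 16.8% of its body (fold enrichment up to 5.53), ahead of Grin2b (0.181%) and Syt1 (0.0592%). Liver genes were marked in 2 of 29 cases (6.90%, 0.654), Cyp3a11 (3.72% covered) and Trf (0.843%), both with no base covered in replicate 1. In the peaks of replicate 1 alone, liver genes were past the threshold below other genes (3 of 29, −12.6 percentage points after rotation, adjusted permutation p = 0.036), with a share of 10.3% inside its rotated range of 3.45 to 27.6. Muscle and heart genes were marked in 4 of 32 cases (12.5%, 0.455), with Ttn, Ryr1 and Ryr2 each covered over less than 0.230% of the body. Blood genes were marked in 3 of 28 cases (10.7%, 0.203), Runx1, Gata1 and Cd3e, the last with no base covered in replicate 2. Endothelial genes were marked in 3 of 18 cases (16.7%, 0.455), Flt1, Cdh5 and Emcn. Of the H3K9 machinery 3 of 26 genes were marked (11.5%, 0.654), Atf7ip, Trim28 and Kdm4b, each by a single peak. The remaining marked genes of the short lists, Cacna1a and Rbfox3 (neuronal) and Nkx2-5 (muscle and heart, 3.15% covered), fall outside the naming rule and were chosen after their values were seen. Over the genome, 1685 of 21938 protein-coding genes (7.68%) held a replicated peak.

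**Figure D3:**
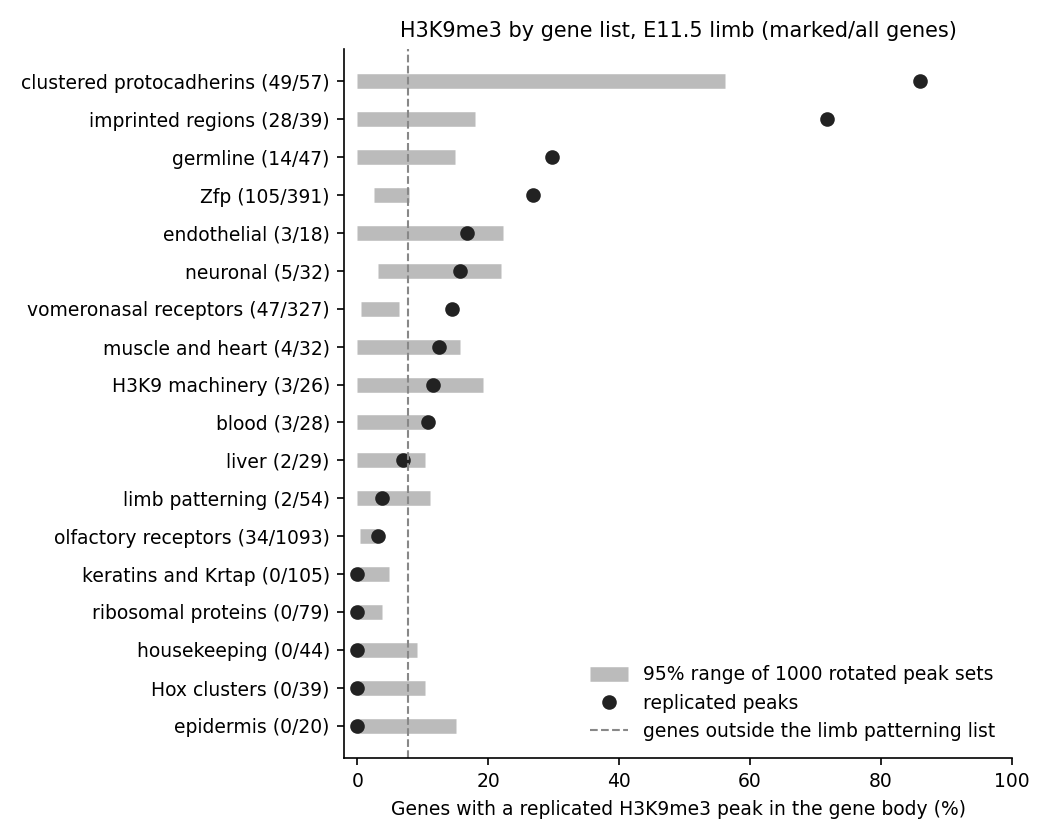
Share of genes with a replicated H3K9me3 peak in the gene body (x axis, percent) for the 18 gene lists, with marked and total genes in brackets. Points are the observed shares, grey bars the 95% range of 1000 rotated peak sets, and the dashed line the share of genes outside the limb patterning list, 7.69%; clustered protocadherins (86.0%) and imprinted regions (71.8%) lie farthest to the right.

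Away from the fixed lists, the gene with the highest covered share among those of at least 5 kb was Mroh2a (chromosome 1, 88226986 to 88262289), covered over 91.4% by 15 replicated peaks (81.9% in replicate 1 and 93.5% in replicate 2). It held 3 of the 5 longest merged peaks, at 88242219 to 88250905 (8687 bases), 88229156 to 88236366 (7211 bases) and 88236614 to 88241753 (5140 bases). Beside it, Ugt1a1, the enzyme that conjugates bilirubin, was covered over 88.9%, and Ugt1a2, whose body contains Ugt1a1, over 36.8%. The others were Asmt (78.3%), the last enzyme of melatonin synthesis, Smok2b (57.03%), Zfp146 (54.8%), Il3ra (47.2%), Zfp873, Repin1 (39.6%) and Polrmt (35.7%). The other two of the 5 longest lay on a contig without a place on a chromosome (6321 bases) and on chromosome 4 at 3079278 to 3084884 (5607 bases), 82435 bases from the TSS of Vmn1r2. The highest fold enrichments on assembled chromosomes were 14.6 at 3117861 to 3119096 of chromosome 18, outside genes and 4315 bases from the TSS of Vmn1r238, 12.1 at Klf14 (chromosome 6, 30957199 to 30958856), 10.996 at Gm21887 (X, 170008958 to 170010046) and 10.7 in Tmem267 (chromosome 13, 119597566 to 119598235), followed by 10.1 on a contig that belongs to chromosome 4 without a position.

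Peaks were found at promoters and exons more often than rotated sets were. Of the 7240 replicated peaks, 253 (3.49%) had their centre in a promoter and 634 (8.76%) in an exon, 2.25-fold and 2.69-fold above rotated sets (1.55% and 3.25%; adjusted permutation p = 0.004 for both). Introns held 28.7%, below the 35.1% of rotated sets (adjusted permutation p = 0.0186), and intergenic sequence 59.0%, against 60.1% (adjusted p = 0.711). Without replicate 2 introns turned to 37.6%, above rotation (adjusted permutation p = 0.024), and intergenic sequence to 50.9%, below it (adjusted p = 0.00266).

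Chromosome 7, home of many Zfp, vomeronasal and imprinted genes, held 1318 replicated peaks and 17.7% of their bases on 5.36% of the sequence, 3.30 times the genome mean. The replicates' own lists gave 2.07 and 2.46 times. After adjustment over 21 chromosomes this was not past the threshold (permutation p = 0.05, adjusted p = 0.524), nor were chromosome 17 (2.33 times, adjusted p = 0.573), chromosome 18 (1.66 times, 0.867), chromosome 4 (1.41 times, 0.887) or X (0.347 times, 0.860). Y held 4 peaks, 0.0476 times the genome mean (adjusted permutation p = 0.042), and with −log10 q of at least 2 it was no longer past the threshold (adjusted p = 0.545). The rotation test treats all gap-free sequence of Y as able to hold peaks. How much of it is unique was not measured, and both pools were of mixed sex. The low value therefore does not show that Y lacks the mark.

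**Figure D4:**
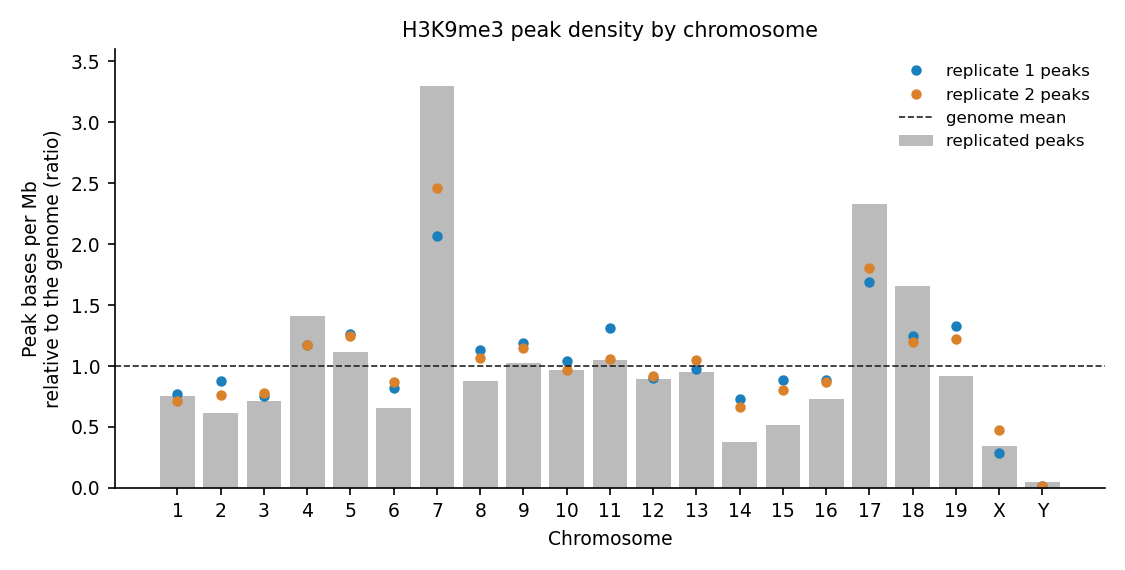
H3K9me3 peak bases per Mb of gap-free sequence relative to the genome (y axis, ratio) for each chromosome (x axis). Bars are replicated peaks, points are the lists of replicates 1 and 2, and the dashed line is the genome mean; chromosome 7 reaches 3.30 and Y 0.0476.

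The bases in replicated peaks were richer in GC and poorer in annotated repeats than rotated sets. GC content was 49.2% against 41.7% (range 40.9 to 42.6), the CpG observed/expected ratio 0.226 against 0.190 (0.180 to 0.199), and the soft-masked share 21.4% against 36.4% (33.5 to 42.7), each with adjusted permutation p = 0.002. Without the peaks centred in promoters and exons, GC stayed at 48.6% and the soft-masked share at 23.4%, while the CpG ratio turned to 0.178, below rotated sets.

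LTR retroelements, dispersed repeats related to retroviruses, were located by their tRNA primer binding sites. Of 174 sites for proline tRNA, 20 (11.5%) lay within 1 kb of a replicated peak, against 0.528% in rotated sets (21.8-fold, adjusted permutation p = 0.00699). The share was 3.58% of 1090 sites for phenylalanine tRNA (39 sites, 6.46-fold, 0.00699) and 7.46% of 67 sites for lysine tRNA 1,2 (5 sites, 14.6-fold, 0.00932). Lysine tRNA 3 (2 of 62 sites, 3.23%, 0.185) and glutamine tRNA (1 of 61, 1.64%, 0.806) were not past the threshold, and leucine tRNA had 2 sites in the genome, neither near a peak. With the peaks of replicate 2 alone the shares for proline, phenylalanine and lysine 1,2 were 22.4%, 14.0% and 26.9% (5.48-, 3.37- and 6.54-fold over rotated sets). Those of replicate 1 alone gave 8.62%, 4.86% and 8.96% (3.96-, 2.27- and 4.17-fold). All of these folds were lower than with the replicated list. Lysine tRNA 3 sites were past the threshold with the peaks of replicate 2 alone (24.2%, adjusted permutation p = 0.0035) and with the pooled list (4 sites, 6.45%, adjusted permutation p = 0.0175). Where a peak had to overlap the site itself, 2 proline sites remained (1.15%, 14.6-fold over rotated sets, permutation p = 0.016, adjusted p = 0.112) and none of the phenylalanine and lysine 1,2 sites. As background, the reversed motifs had no site in the genome except 1 for leucine.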

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

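Chosen only after the result was seen were the tests of weak peaks near the cutoff, of the last exons of other genes, and of the repeat content that remains in unique sequence.

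Replicated peaks were dense on contigs that have no place on a chromosome, which no comparison of location used. This density drew attention because it lies in data outside those comparisons, and there were no control peaks to set it against. Of the 7475 replicated peaks, 235 (3.14%) lay on 20 of 44 such contigs, with up to 52 peaks on a contig and a highest fold enrichment of 10.1. They covered 28622 bases per Mb of gap-free contig sequence, against 909 on assembled chromosomes, a ratio of 31.5. Unique sequence was measured on assembled chromosomes only, so whether reads shared between repeated sequences raised this density was not tested. The replicates' own lists held 248 peaks (0.921%) and 319 peaks (0.576%) on these contigs.

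Zfp genes carried replicated peaks in the last exon (ratio of last exon to rest 9.12). If last exons of all genes carried peaks, other protein-coding genes would have a ratio of at least 50% of that, and it was 1.31. If reads shared between similar Zfp genes made the peaks, most covered last exon bases would lie in repeated sequence. Of these bases, 98.2% start a sequence of 32 bases found a single time in the assembled genome. This cannot decide the question, since 95.9% of the bases in all replicated peaks did so too. Only exact matches were counted, so that near copies of a sequence passed as unique. The tables argue against the first explanation as the whole cause, while reads shared between similar Zfp genes stay open. With 1 group in the design, no biological explanation was tested, and differences between the immunoprecipitate and the control that depend on sequence stay open.

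Replicate 2 listed 2.06 times as many peaks as replicate 1. If replicate 2 had called further down a shared ranking, at least 50% of the peaks of replicate 1 would be found in it. Of them, 21.6% were, under the bound of 25% set in advance. However, a q below 0.05 was given for 18.4% of replicate 1 peaks, and weak peaks can lower the overlap under a shared ranking too. Among the strongest 10% of replicate 1 peaks the share was 48.8%, and 39.8% at −log10 q of at least 2 in both lists. Both lie between the bounds, so the test cannot decide and a shared ranking stays open. Among peaks with −log10 q of at least 2 the ratio was 6.12, but q is computed per list and depends on depth, so that a contribution of weak peaks near the cutoff stays open. So do sequencing depth and the quality of the immunoprecipitation, because the lists hold no read counts, and no biological explanation was tested.

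Replicated peaks held few soft-masked bases, 21.4% against 36.4% in rotated sets. Peaks that cannot be called in sequence that is not unique are a candidate explanation for most of this, since 95.9% of peak bases and 81.3% (SD 2.44 over 20 rotated sets) of rotated bases start a unique sequence of 32 bases, and against these 20 sets, with 35.9% soft-masked, the deficit was 14.5 percentage points over all bases and 4.35 among unique bases. Uniqueness by exact match of 32 bases does not account for the remainder, as 20.0% of unique bases in peaks were soft-masked, below the lowest of the rotated sets, 23.1%. Near copies of a repeat count as unique by this measure. Whether peaks could not be called in such copies either was not tested, so this explanation stays open for the remainder too. Peaks centred in promoters and exons are not the whole cause, since without them the share was 23.4%, still below the rotated range of 33.5 to 42.4. No biological explanation was tested.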

How the results depend on the processing

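The alternatives that test the share of a list alone, or that use replicated peaks overlapped by both replicates, were chosen after the data were seen. Of 288 recomputed values for the main results, 219 kept their direction and their side of the threshold or stayed within their interval. The overlap of both replicates, the calls for promoters and exons, Zfp genes, protocadherins and imprinted regions, the last exons of Zfp genes (ratio 5.81 to 11.1) and GC, CpG and soft-masked content kept their call in every alternative run for them, except that the CpG ratio turned below rotated sets without the peaks in promoters and exons. For last exons the call rests on unadjusted p. The largest ratio, 11.1 with −log10 q of at least 2, was the weakest call (permutation p = 0.047, rotation test, rotated range 0 to 10.5). No paired analysis was possible because there was 1 group. The lists hold no read counts, so what depth limits could not be measured. Of 159 alternative values for 53 named genes, 111 stayed and 48 moved. Where no reason is given, the cause was not tested.

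Without either replicate, introns held 32.5% to 37.6% and intergenic sequence 50.9% to 58.9% of peak centres, 6466 to 8190 protein-coding genes held a peak, 3 to 4 lists lay above and 1 to 4 below other genes (the latter with their own shares inside their rotated ranges), and the last exon ratio of other genes was 1.42 to 1.496. In percentage points above the comparison, after the rotated mean, the lists gave −8.83 to −1.28 for olfactory, −5.70 to 6.005 for vomeronasal, −10.7 to −5.25 for keratin, −3.42 to 10.1 for Hox, 10.3 to 16.5 for germline, −4.89 to 10.002 for limb patterning, −8.59 to −5.15 for housekeeping, −12.6 to 1.37 for liver and 0.111 to 0.720 for epidermal genes. Glutamine sites gave 1.64% to 6.56%.

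In the series lists, the share of replicated peaks found in both replicates was 63.7% at 1 bp, 46.7% at a reciprocal 50% and 78.0% at −log10 q of at least 2. It was 68.1%, 58.7% and 78.8% in replicate 1, and 95.5%, 79.8% and 99.1% in replicate 2. For pooled peaks found in both it was 48.3%, 34.6% and 74.2%. The rho of fold enrichment was 0.177 at −log10 q of at least 2 (Pearson's r 0.331), and that of −log10 p 0.284 (r 0.800).

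With −log10 q of at least 2, lists gave −0.0449 points for olfactory, 0.0705 for limb patterning, −1.41 for liver, −2.18 for muscle and heart, −1.38 for blood, −2.43 for endothelial and −2.41 for H3K9 machinery genes. The last exon ratio of other genes was 0.903, lysine 3 and glutamine sites stood at 0%, 0 chromosomes passed, and 10 lists lay below other genes. With the pooled list, olfactory genes gave −0.0594 and liver genes −0.0115 points, and with peaks overlapped in both replicates −0.153 and −3.92. With the 50% of peaks of highest fold, muscle and heart genes gave −1.60 points and glutamine sites 0%.

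Within 2 kb of a TSS, vomeronasal genes gave 1.66 points, limb patterning −1.75, neuronal −1.74, muscle and heart −1.74 and endothelial −1.72, and 9 lists lay below. At 10% of the gene body, the values were −0.166 for olfactory, 0.00935 for vomeronasal, −0.558 for germline, −0.568 for limb patterning, −0.579 for liver, −0.589 for muscle and heart, −0.698 for blood, −0.594 for endothelial and −0.552 for H3K9 machinery genes, with 3 lists above and 12 below. All 10, 9 and 12 lists below at these 3 settings had no marked gene, and so had the 5 in the main result. Fewer genes held a peak, 457 at −log10 q of at least 2, 949 with the 50% of highest fold, 378 near a TSS and 126 at 10% of the body, since each setting asks for more.

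Tested by the share of the list alone, the values were −0.901 for keratin, −1.77 for Hox, −0.984 for ribosomal, −2.68 for housekeeping and −4.25 for epidermal genes, with 0 lists below. Against random lists matched on gene length they were −2.31, −3.52, −2.79, −4.88 and −6.57, also with 0 below, and −0.178 for olfactory genes. Fisher's exact test gave −7.69 for Hox, −7.70 for housekeeping and −7.69 for epidermal genes, no longer past the threshold, −4.81 for olfactory and −0.785 for liver genes, with 3 lists below. Requiring a peak to overlap the primer binding site left 0 tRNAs past the threshold, with 1.15% of proline sites and 0% for phenylalanine, lysine 1,2, lysine 3 and glutamine.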

Other observations

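The tests of arrayed families and of chromosome ends were chosen only after the result was seen, from the windows with the most peak bases, and the families were picked from those windows.

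Several tandem gene families outside the fixed lists carried H3K9me3. Of 71 genes in the Ugt1a, Ceacam, Scgb and Psg families, 25 (35.2%) held a replicated peak, against 2.91% in rotated sets (95% range 0 to 12.7). All 9 Ugt1a genes, whose annotated bodies overlap and which encode enzymes that conjugate bilirubin and drugs, were marked, as were 8 of 15 Ceacam genes (53.3%), cell surface glycoproteins, and 6 of 34 Scgb genes (17.6%), which encode secretoglobins. Of the Psg genes, pregnancy-specific glycoproteins beside Ceacam on chromosome 7, 2 of 13 were marked (15.4%). Because these families were picked for the peaks they held, the values describe them and do not test whether tandem arrays outside the fixed lists carry the mark, which stays open.

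Several chromosome starts, which lie beside the centromere in the mouse, were also dense in H3K9me3. The first gap-free Mb of chromosomes 1 to 19 and X held a mean of 9262 replicated-peak bases per Mb, against 884 in rotated sets (95% range 239 to 2910), and 14 of the 20 were above the genome mean. Chromosome 3 held 38630 bases, chromosome 4 28981 and chromosome 11 21385, while chromosomes 1, 14 and X held 0. The mean includes the windows that led to it. Without the 6 chromosomes whose start was among the 20 windows with the most peak bases, the other 14 held a mean of 2908 bases, inside the rotated range of 175 to 3076 (permutation p = 0.062). Whether the mark extends from the centromere end in general stays open, and copies of satellite sequence in the assembly were not separated from it.

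Marked Zfp genes had marked neighbours more often than randomly drawn Zfp genes did. Of the 77 Zfp genes with a replicated peak in the last exon, 37.7% had a nearest Zfp gene that was marked too, against 19.6% in 10000 random draws of as many Zfp genes (95% range 9.09 to 29.9; p = 0.003, permutation test). This fits the hypothesis that marked Zfp genes cluster, and whether single blocks of the mark span neighbours was not tested.

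Beyond the protocadherin window, the 1-Mb windows with the most peak bases were 88 to 89 Mb of chromosome 1 with Ugt1a and Mroh2a (70 peaks, 2.95% of all replicated-peak bases), 3 to 4 Mb of chromosome 3 (61 peaks, 1.60%), 17 to 18 Mb of chromosome 7 with Ceacam and Psg genes (113 peaks, 1.58%), 12 to 13 Mb of chromosome 7 with 7 Zfp and 12 vomeronasal genes (88 peaks, 1.42%) and 33 to 34 Mb of chromosome 7 with Scgb genes (91 peaks, 1.30%). Of the replicated peaks, 2854 did not meet a rule of 50% of either peak in both replicates, and all 4621 pooled peaks that met it were in the replicated list.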
